A study of Homo sapiens with 6 samples.

How the data were processed

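Gene expression was measured in K562, a human cell line established from chronic myeloid leukemia. Cells were infected either with a scramble virus (control) or with a virus carrying a hairpin against HNRPDL, an older name of HNRNPDL, which encodes an RNA-binding protein of the hnRNP family. GFP-positive cells were sorted 72 h after infection, and total RNA was labelled with Cy3 and hybridised to 1-colour Agilent whole human genome arrays. The labels give 3 arrays per group, numbered 1 to 3 in each, and the submitters describe them as biological replicates.

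The deposited table holds log2 values for 120932 probes in each of the 6 arrays; that the scale is log2 was read from the values and is not stated by the authors. Scanner images were read with Agilent Feature Extraction 10.7.3, per the submitters' processing notes. The background correction, the normalization and any averaging of repeated spots are not given in the sources used here. The values of the 6 arrays, sorted by size, differed by at most 0.184 log2 at any rank, as they do after quantile normalization, and array medians lay between 4.91 and 4.93. Such scaling makes the arrays equal in overall brightness, so a change that moved most transcripts one way would not be visible. The table has no detection flags.

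Of the probes, 120864 carry custom IDs made of a number and a design number, and 68 are Agilent control probes. No custom ID matched any identifier in the reference gene table (0 matches), and the deposited table does not pair the IDs with genes. Results are therefore given per probe, no custom probe is named by a gene, and at most 2 IDs are printed for each direction. The level of HNRNPDL, which would have checked the labels, was not analysed here. The 31 gene lists (966 genes) fixed before the data were examined were not tested, and neither were the alternatives that needed gene names. Several control probes name a gene in their ID, of which 4 are for human GAPDH and human PGK1.

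Analyses were run in R 4.3.3 with limma 3.58.1. The test, the filter, the naming rule and the alternatives listed next were fixed before the data were examined. Custom probes were tested where their mean over all 6 arrays was at or above the 40th percentile of all probe means (3.73 log2), which left 72516 probes. Values were used as deposited and no further normalization was applied. The main test was limma's lmFit and eBayes with the group as the single term, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of 0.05; a fold threshold of 2, the one in the design text, was added to it. The design text names a Student's t-test with p and fold thresholds, and this methods' t-test was run on the same values as an alternative. Further alternatives were repeated quantile normalization, a shift of each array to one 75th percentile or one median, no filter, a 60th percentile filter, eBayes with trend and robust settings, array weights, the replicate number as a block, and leaving out each array in turn. Fits with the block and another setting together, fits without the third array of both groups, and the counts over replicate pairs were added after seeing the data.

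The rule for named items took the 10 largest rises and falls past the test with no overlap between groups and a mean in one group at or above the median of all probe means (4.83). No probe met it. Instead 2 rises and 2 falls were chosen after their values were seen, by the same rule with the unadjusted p under 0.05 in place of the adjusted one.

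The replicate numbers were checked for pairing by correlating the deviations of the arrays from their group means over the tested probes. Arrays with the same number correlated at 0.597, 0.567 and 0.808 for numbers 1, 2 and 3, all above the 0.1 set beforehand, and the numbers were taken as pairing the arrays. Unmatched numbers 1 and 2 correlated almost as highly, at 0.509 and 0.526, so the pairing of these numbers rests mainly on their shared distance from the third arrays. The labels name no shared day or batch. Values are therefore given with the replicate block beside the main ones where it changes them. No 2 arrays were copies: the closest arrays shared 25 identical values among the 120864 custom probes. Control probes were compared with an exact two-sided permutation test of the group labels, which cannot go below p = 0.1 with 3 arrays per group.

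The fits were tested on simulated data with the real probe means. Replicate shifts were averaged over both groups and given equally to both. Noise was drawn from a normal distribution, with each probe's SD taken from the fit with block, trend and robust. In these data 50 probes were changed by each of 1, 2, 3 and 4 log2 units among 72516. The fit with the group alone recovered 0, 12, 25 and 35 of them, with 0 false calls. The fit with the block recovered 6, 43, 48 and 49, with 2 false calls. The fit with block, trend and robust recovered 35, 46, 48 and 49, but with 44 false calls, more than its threshold allows. The fit without the third arrays recovered 0, 10, 29 and 41, with 2 false calls. The block removes equal shifts in full, but the real shifts were not equal in both groups. These counts therefore do not give the recovery or the false calls in the real data. Precision is limited by the 3 arrays per group, and for dim probes by the background.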

Results

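Transcript levels were compared between K562 cells that received a hairpin against HNRPDL and K562 cells that received a scramble control, to find which transcripts differ when this RNA-binding protein is silenced. Each group held 3 arrays taken 72 h after infection. The median of the deposited log2 values lay between 4.91 and 4.93 in every array and the 75th percentile between 7.70 and 7.72. Background was read from Agilent's negative control probe, which lay between 1.86 and 1.91, and from the empty dark corner spots, between 1.94 and 2.13. Between 21.5% and 25.3% of the 120864 custom probes were at or below the dark corner value of their array. After the filter on dim probes 72516 were tested.

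The third arrays differed from replicates 1 and 2 more than the groups differed from each other. The third arrays of the scramble and shHNRPDL groups correlated with each other at 0.986 over the custom probes, and with the other arrays of their own group at 0.961 to 0.967. Replicates 1 and 2 correlated at 0.985 in the scramble group and at 0.983 in the shHNRPDL group, above the 0.979 between the groups for replicate 1 and the 0.980 for replicate 2. In a principal component analysis of the tested probes, the first component, with 65.0% of the variance, set the third arrays apart from the rest, and the second, with 17.9%, set the groups apart. The mean of the third arrays was at least 2-fold from that of replicates 1 and 2 for 13311 probes (18.4%), against 2069 probes (2.85%) between the groups. Each group held 1 such array, so their number is balanced over the comparison, but the size of the shift is not. Across probes the shifts in the scramble and shHNRPDL groups correlated at 0.808. They were alike but not equal, and the unequal part enters the group difference.

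**Figure D1:**
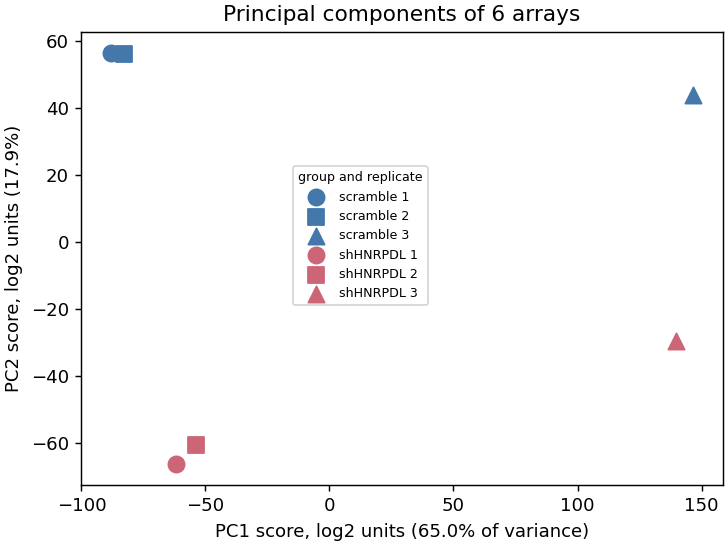
Scores of the 6 arrays on the first 2 principal components of 72516 tested probes, in log2 units. Colours are groups and marker shapes are replicate numbers; the third arrays (triangles) lie to the right, and the scramble arrays lie above the shHNRPDL arrays on the second component.

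Most E1A control probes were higher in the third array of both groups. E1A probes, which detect spike-in RNAs added to the sample in Agilent's labelling procedure, were higher in the third array than in replicates 1 and 2 by a median of 0.89 log2 in the scramble group and 0.98 in the shHNRPDL group, for 9 of 10 probes in each. The DCP control probes showed medians of 0.92 and 1.08. Some read close to an E1A probe, such as DCP_1_0 at 17.38 and E1A_r60_1 at 17.39 in scramble replicate 1. What the DCP probes detect is not given in the sources used here, so they are not counted as separate evidence. The tested probes had medians of -0.07 in both groups. Between the groups the E1A probes had a median difference of 0.01 log2.

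**Figure D2:**
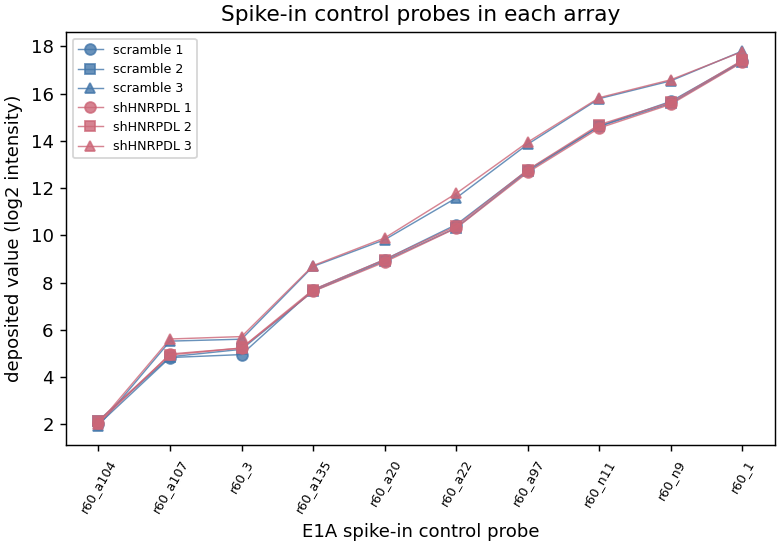
Deposited log2 values of the 10 E1A spike-in probes, ordered by their mean in the scramble group, with 1 line per array. The lines of both replicate 3 arrays (triangles) run above those of the other 4 arrays at 9 of the 10 probes.

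For human GAPDH, a glycolytic enzyme often used as a reference, the group means differed by 0.004 log2 at the 3' probe and by 0.051 at the 5' probe. The exact permutation test used here cannot go below p = 0.1 with 3 arrays per group, so it cannot show a difference at the 0.05 level. The probe at its 3' end read 16.48 ± 0.38 in the scramble group and 16.48 ± 0.20 in the shHNRPDL group (SD, n = 3 each, exact permutation p = 1), and the 5' probe read 13.77 ± 0.32 and 13.82 ± 0.16 (exact permutation p = 1). Human PGK1, another glycolytic enzyme, read 14.92 ± 0.11 and 14.92 ± 0.04 at the 3' probe and 10.24 ± 0.33 and 10.30 ± 0.10 at the 5' probe (exact permutation p = 1 for both). All 4 human probes were lower in shHNRPDL in pairs 1 and 2, by at most 0.14 log2, and higher in pair 3, by 0.15 to 0.33. Without scramble replicate 3 the GAPDH differences were -0.21 and -0.13 log2 and the PGK1 differences -0.07 and -0.13. That comparison keeps shHNRPDL replicate 3, so it mixes the shift of that array with the group difference. Without both replicate 3 arrays the GAPDH differences were -0.099 and -0.042 log2 and the PGK1 differences -0.085 and -0.072.

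Between the groups, most tested probes differed little in mean value and a minority differed by 2-fold or more. The 25th and 75th percentiles of the log2 fold changes were -0.17 and 0.19, and the 1st and 99th were -1.18 and 1.06. Mean values were at least 2-fold higher in the shHNRPDL group for 879 probes and at least 2-fold lower for 1190. At 4-fold the counts were 52 higher and 114 lower, and at 8-fold 3 higher and 14 lower.

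None of these differences passed limma's test with the group as the single term, or with a replicate block added, over the 72516 tested probes. With the group as the single term, 0 of 72516 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.183. An unadjusted p under 0.05 was reached by 5146 probes (7.10%), of which 2443 were higher and 2703 lower in shHNRPDL. The larger direction changed with which replicate 3 array was left out. Without scramble replicate 3 the counts were 3897 higher and 5647 lower. Without shHNRPDL replicate 3 they were 3622 higher and 2824 lower. Each of these fits keeps the replicate 3 array of the other group, so it mixes the shift of that array with the group difference. Without both replicate 3 arrays, a setting added after seeing the data, the unadjusted counts were 11457 higher and 11601 lower. With the replicate number as a block, limma gave 16794 probes with an unadjusted p under 0.05 (23.2%), 8218 higher and 8576 lower. Again 0 passed the adjustment, with a smallest adjusted p of 0.059, but the result depends on the filter: with the 60th percentile filter, a combination added after seeing the data, the block gave 6011 probes past the test, 2762 higher and 3249 lower, of which 839 were at least 2-fold apart. The median residual SD per probe was 0.366 log2 without the block and 0.140 with it. The methods' t-test gave 1015 probes with p under 0.05 and at least a 2-fold difference, 401 higher and 614 lower, and 0 after Benjamini-Hochberg adjustment. Without the dim-probe filter the methods' t-test gave 1377 such probes among all 120864, 540 higher and 837 lower, of which 1 passed the adjustment.

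Some other settings did give calls. With array weights estimated from the data, an alternative fixed before the data were examined, limma called 27854 probes over the 6 arrays, 13867 higher and 13987 lower in shHNRPDL, and 3399 of them were at least 2-fold apart. In the scramble and shHNRPDL groups these weights were 0.085 and 0.113 for replicate 3, 1.37 and 1.30 for replicate 1, and 6.64 and 8.77 for replicate 2. The calls thus rest mainly on replicate 2 of each group, and this fit was not run on the simulated data. The next 2 settings were chosen after seeing the data. Without both replicate 3 arrays, limma called 6596 probes, 3062 higher and 3534 lower in shHNRPDL, and 1817 of them were at least 2-fold apart, 806 higher and 1011 lower. With the block together with eBayes' trend and robust settings it called 6776 probes, 3118 higher and 3658 lower, of which 1278 were at least 2-fold apart, 476 higher and 802 lower. Both lists shared 3811 probes, all in the same direction, but the fits share replicates 1 and 2. On simulated data the block, trend and robust fit made more false calls than its threshold allows. Those data were drawn once with few probes changed, so they do not give the share of false calls in the real list. The count with block, trend and robust fell to 87 without replicate 2, to 171 without replicate 1 and to 0 with no filter, and rose to 20108 without replicate 3.

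The differences were next compared between replicate pairs, which have no array in common, as a measure chosen after seeing the data. Across probes, which are not independent replicates, the log2 difference of shHNRPDL from scramble in pair 1 correlated with that in pair 2 at r = 0.546 (Spearman 0.609). Pair 3 correlated with pair 1 at r = 0.308 (Spearman 0.302) and with pair 2 at r = 0.313 (Spearman 0.321). Among probes above the 60th percentile the 3 correlations were 0.835, 0.463 and 0.481. The difference had the same sign in all 3 pairs for 48.1% of the probes, 18533 higher and 16329 lower, where independent signs would give 25%.

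A set of 565 probes was at least 2-fold apart in the same direction in all 3 pairs, 177 higher and 388 lower in shHNRPDL. Probes at least 2-fold apart in all 3 pairs with 1 pair opposite to the others numbered 27 for pair 3, 13 for pair 2 and 12 for pair 1. Lower probes made up 68.7% of the 565. With replicates 1 and 2 alone 1950 probes met the criterion, and the lower ones made up 55.9%, so the size of the excess of lower probes rests in part on the third arrays.

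The third pair also served as a separate reading of the calls made without it. Of the 6596 probes called from replicates 1 and 2, 5573 (84.5%) differed in the same direction in pair 3, against 58.9% of the 65920 probes not called. Of the 1817 called probes at least 2-fold apart, 1628 (89.6%) did. The called probes had a median absolute log2 fold change of 0.78 in replicates 1 and 2, and a median of 0.39 in the called direction in pair 3.

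**Figure D3:**
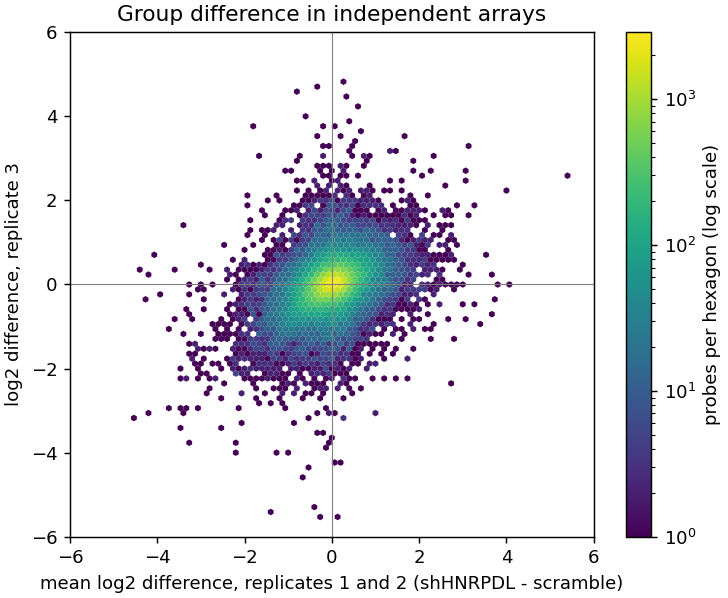
Each tested probe's log2 difference of shHNRPDL from scramble, as the mean of replicates 1 and 2 (horizontal) against replicate 3 (vertical), with colour for the number of probes per hexagon on a log scale; 12 probes lie outside the plotted range of 6 log2 units. The cloud is tilted along the diagonal, with a correlation of 0.353.

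The probes with the largest differences among those that met the naming conditions illustrate these values. They were chosen after their values were seen. The choice required no overlap between the groups, which fixed their direction in every pair. None passed limma's test with the group alone or with the block under the 40th percentile filter. CUST_141003_PI430048170 was among the largest falls, at 11.36 ± 0.25 in scramble and 7.29 ± 0.83 in shHNRPDL (SD, n = 3 each). Its log2 fold change was -4.07 with an SE of 0.43, a 16.7-fold lower level, with a limma adjusted p of 0.213, of 0.059 with the block, of 0.0097 with the block and the 60th percentile filter, of 0.0063 with block, trend and robust, of 0.000185 with array weights (-4.54 log2) and of 0.031 without both replicate 3 arrays (-4.54 log2). It was lower in all 3 pairs, with log2 differences of -4.49, -4.59 and -3.11. CUST_143157_PI430048170 had the largest rise, from 2.74 ± 1.56 to 7.18 ± 0.26, a log2 fold change of 4.44 with an SE of 0.74 and a limma adjusted p of 0.239 (0.069 with the block, 0.015 with block, trend and robust, 0.000185 with array weights at 5.12 log2, and 0.031 without both replicate 3 arrays at 5.36 log2). It was higher in the 3 pairs by 5.65, 5.07 and 2.61 log2. Without scramble replicate 3 it was higher by 5.34 log2, so that array made the rise smaller. Its scramble values were below the dark corner spots in 2 of 3 arrays, replicates 1 and 2, so the differences from them are not exact. Against those spots it was at least 19.6-fold higher in shHNRPDL over all arrays, and at least 35.1-fold higher without the third arrays.

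CUST_24855_PI430048170 read 2.39 ± 0.23 in scramble and 5.77 ± 1.66 in shHNRPDL, a log2 fold change of 3.39 with an SE of 0.79 (limma adjusted p = 0.365, 0.079 with the block, 0.023 with block, trend and robust, 0.0032 with array weights at 3.21 log2, and 0.069 without both replicate 3 arrays at 3.98 log2). It was higher in all 3 pairs, by 2.20 to 4.99 log2. Leaving out 1 array gave 2.47 (without shHNRPDL replicate 1) to 4.09 log2 (without shHNRPDL replicate 3). Its scramble values of 2.166 to 2.625 lay close above the dark corner spots of those arrays, at 1.94 to 2.13, so its fold change is limited by the background. CUST_94007_PI430048170 had the largest fall, -6.45 log2 with an SE of 2.28 (limma adjusted p = 0.591, 0.170 with the block, and 0.076 with block, trend and robust), but 1 array set its size. With array weights its log2 fold change was -3.54 (limma adjusted p = 0.0026), and without both replicate 3 arrays it was -3.61 (limma adjusted p = 0.031). It read 13.93 in scramble replicate 3, 5.57 and 5.14 in scramble replicates 1 and 2, and 1.71 to 1.80 in the shHNRPDL arrays, all at or below their dark corner spots. Against those spots it was at least 70.2-fold lower in shHNRPDL over all arrays, and at least 9.74-fold lower without the third arrays.

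**Figure D4:**
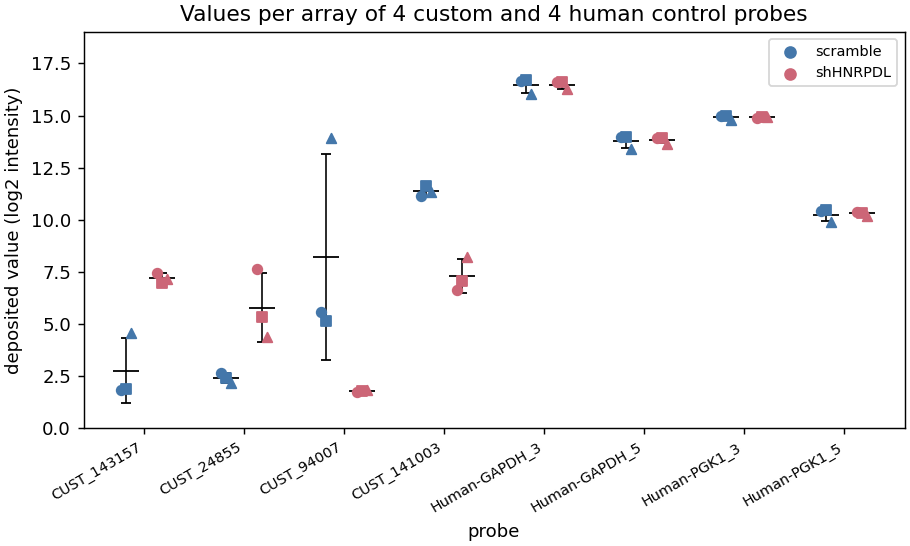
Deposited log2 values per array of the 4 custom probes named in the text (design number left off) and of the 4 human GAPDH and PGK1 control probes. Circles, squares and triangles are replicates 1, 2 and 3, horizontal marks are group means and bars are SD; the 4 control probes overlap between groups, and CUST_94007 has 1 scramble array at 13.93.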

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

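The number of probes past the test was 0 in the fit with the group alone. It stayed 0 with repeated quantile normalization, the 75th percentile or median shift, no filter, the 60th percentile filter, trend and robust eBayes, the methods' t-test, the replicate block, and without any 1 array. It was 27854 with array weights (3399 at least 2-fold), a fit that rests mainly on replicate 2 of each group. Of the settings added after seeing the data, it was 6596 without both replicate 3 arrays (1817 at least 2-fold), 6776 with block, trend and robust (1278) and 6011 with the block and the 60th percentile filter (839), and 0 with the block and no filter.

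Probes with an unadjusted p under 0.05 numbered 5146 (1388 at least 2-fold). They numbered 16794 with the replicate block, 35690 with array weights (3530), 23058 without both replicate 3 arrays (2624), 18720 with block, trend and robust, 14934 with the block and the 60th percentile filter (914), 16974 with the block and no filter (2257), and 780 at least 2-fold with the 60th percentile filter. Leaving out 1 array gave 2819 (without scramble replicate 2) to 9544 (without scramble replicate 3), and 1181 to 2920 at least 2-fold. The count with block, trend and robust ran from 87 to 20108 without 1 replicate number (87 to 2531 at least 2-fold) and was 0, also at least 2-fold, with no filter. Probes at least 2-fold apart in the same direction in all 3 pairs numbered 565, and 321 with the 60th percentile filter, which tests fewer probes; with 1 pair left out, and so 1 condition fewer, they numbered 754 to 1950. The cause of the other changes was not tested. The 4 named custom probes kept their direction in every alternative that tested them, but they were chosen with no overlap between the groups. Leaving out arrays could therefore not reverse them. The 4 human control probes moved by less than 1 SD pooled over the groups under each scaling or left-out array. Without scramble replicate 3, but with shHNRPDL replicate 3 kept, these control probes moved by more than the shHNRPDL group's own SD. Dim probes are limited by the background, and the table has no detection flags.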

Other observations

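The tests of the third arrays and of a swap were chosen only after the result was seen, and the probes used in the test of the floor were changed after its first value was seen; the tests of consecutive probe numbers, of brightness and of other splits were written before theirs.

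The third arrays of both groups stand apart in the same way. The shift of the third array from replicates 1 and 2 in the scramble group correlated at 0.808 across probes with that in the shHNRPDL group. The E1A spike-ins, which do not come from the cells, shifted with them, by 0.89 log2 in the group with the smaller median, which is consistent with labelling, hybridization or scaling that differed between arrays for at least part of the shift. Lower RNA integrity stays open, because the gap between 3' and 5' probes was smaller in the third arrays for GAPDH (by -0.089 log2 on average) and larger for PGK1 (by 0.29). A difference between cultures also stays open and was not tested, since the labels name no slide, day or batch.

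The differences between groups were partly shared by replicate pairs that have no array in common. Independent noise in each probe is argued against by these correlations and, more weakly, by probes with consecutive numbers. Their log2 fold changes correlated at 0.078, above the highest of 1000 shufflings (0.015). The correlation was 0.041 at a distance of 2, 0.013 at distances of 5 and 10, 0.001 at 100 and 0.012 at 1000. Between consecutive numbers the shift of the third arrays correlated at 0.095 and the probe level at 0.172. Likeness of neighbours is thus not particular to the group difference. A trend with brightness left by the normalization is argued against, since the lowest correlation between pairs was 0.307 after the trend on the probe mean was removed. A swap of the third arrays between the groups is argued against by the positive correlation of pair 3 with the other pairs, of which the lower was 0.308. A response of the transcripts to HNRPDL silencing stays open as a hypothesis, and so does any handling difference between the scramble and shHNRPDL samples that was repeated in each pair.

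Jumps between the floor and low signal may produce large fold changes in these data, as some control probes read near 2 in some arrays and above 4 in others. Among the 565 probes at least 2-fold apart in the same direction in all 3 pairs, 42 (7.43%) had a group mean under 3, but the filter on the mean removes many probes of that kind. With no filter, 204 of 731 such probes (27.9%) had a group mean under 3, and 103 of the 205 with 1 pair opposite to the others did (50.2%), so such jumps stay open as the source of part of the set. Both group means were at or above the 60th percentile for 249 of the 731 and for 4 of the 205. For the 463 of the 565 with a tested neighbour in number, 54.0% of the neighbours had a difference of the same sign, with a median of 0.03 log2 in that direction.

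The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The fit with the group alone gave 0 probes past the test for the real split and 0 at most for the others, so 10 of 10 splits gave as many. For an unadjusted p under 0.05, 5 of the 10 splits gave as many as the real 5146, the highest of the others being 16749, from a split that keeps scramble replicates 1 and 2 together with shHNRPDL replicate 1 against an arm holding both replicate 3 arrays. That count, over 3 times the real one, points to the structure by replicate number. Among the splits that, like the real one, part all 3 pairs, the highest other count was 704. With block, trend and robust the real split gave 6776 (1 of 10) and the highest other 0, but 6 of the others part only 1 pair, so their difference rests on that pair; only 3 others part all 3 pairs, too few to set against the real one.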
